A study of Homo sapiens with 4 samples.

How the data were processed

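Total RNA of Huh7 cells was extracted with Trizol, amplified to aminoallyl RNA and coupled to the dye Cy5, with 1 dye per array, per the labels' protocols. The cells stably carried a scramble shRNA or an shRNA against ACOT12. The values used were the intensities on a linear scale that the authors deposited, 1 column for each of the 4 samples, and every column was matched to its sample by name. Scanner, background correction and normalization were not given in the sources used here. Some deposited intensities were below 0, as after a background subtraction, and all values under 200 on each array were whole multiples (within 0.02 of a step) of 1 step of about 1 that differed between arrays, so the values carried 1 multiplicative factor per array. No common distribution had been imposed: the log2 medians of the arrays differed by 0.46.

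Intensities under 1 were set to 1 (9, 87, 264 and 3 probes on scramble replicates 1 and 2 and shACOT12 replicates 1 and 2) and converted to log2. By a rule fixed before the data were examined, arrays whose log2 medians differed by more than 0.1 were quantile normalized, which applied here. Quantile normalization forces the arrays onto 1 distribution and would hide a shift of most genes. The median log2 fold change of all genes was 0.0078 after it and between -0.0024 and 0.035 under the other scalings. No detection flags were used, so a probe near the bottom of the scale was not marked as such.

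Probes were named through a table of the platform's annotation. Of 28264 probes, 25893 had 1 gene symbol, 0 had several and 2371 had none and are unnamed here. All 25893 symbols were matched by gene identifier to a table of RefSeq genes (assembly GRCh38.p14, used for names only), which changed 0 of them. No build of the platform was named, so no coordinates are given. Each gene was represented by its probe with the highest mean over all arrays, giving 19090 genes, 13339 with 1 probe and 5751 with several. None of the unnamed probes passed the threshold in a fit by probe with limma; 47 had an unadjusted p under 0.05.

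The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings), without a block for the replicate number, and p-values were adjusted over all genes by the Benjamini-Hochberg method with a threshold of 0.05. The residual degrees of freedom were 2 and the prior added 4.69. Gene lists with at least 8 measured genes were tested with camera (two-sided, preset inter-gene correlation of 0.01, adjusted over 34 lists), beside camera with an estimated correlation and fry. Camera with an estimated correlation rests on the residual degrees of freedom, here 2, so its p can rise also where members do not move together. The lists covered acyl-CoA thioesterases, acetyl-CoA, lipid, hepatocyte, epithelial, mesenchymal, chromatin, proliferation, signalling and stress genes and markers of 5 other cell types or lineages, and held 788 different measured genes.

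The rule for named genes was fixed before the data were examined: ACOT12 first, then the genes with the largest change among those past the threshold whose groups did not overlap and whose brighter group reached the median of all genes. With fewer than 3 genes past the threshold it turned to the 6 genes per direction with the smallest unadjusted p and a difference of at least 2-fold. The conditions on overlap, brightness and symbol were kept for these, a reading of the rule made after the data were seen. TWIST2, CDH1, CDH2, VIM, AFP and ALB were always given. For a list with no member past the threshold, the 2 members with the largest change and a mean at or above the median were named. The 16 lists described with members were picked after the list results were seen, from the themes of the study and the lists with an unadjusted camera p under 0.05. Named after their values were seen were ACOT6 and THEM5, dim on all arrays, and GABRA2, ANKRD24, DSP and the other genes with near-zero values on 1 or 2 arrays.

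The fit was tested on simulated data for 19090 genes, with 200 genes changed in each of 10 runs and variances drawn from the fitted prior. It called 0.470% of genes changed by 1 on the log2 scale, 27.4% of those changed by 2 and 83.7% of those changed by 3, and 53 of 188900 unchanged genes. This way of drawing variances replaced an earlier one, with heavier tails around each gene's own variance, after the first result had been seen; the earlier one called 0%, 21.0% and 83.8%. In 20 simulated data sets with the histone list shifted by 0.5 and independent genes, camera called that list in 20 and other lists in 0 of 660 tests. On the arrays the shift of that list was 0.40 and the estimated correlation between its members 0.206. These simulations therefore do not show how often camera calls rightly or wrongly on these arrays.

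The alternatives tried were an intensity trend or a robust prior in eBayes, the replicate number as a block, 75th percentile scaling, cyclic loess, leaving out the dimmest 30% of genes, a floor at the 20th percentile, the mean of a gene's probes, 1 row per probe, leaving out each array in turn, a plain test per gene without moderation, treat against a log2 fold change of 0.5, an unadjusted threshold with a 2-fold limit, and the other list tests. With 1 row per probe, each probe of a gene counted as a separate list member, which can make camera's p too small. Chosen after the data were seen were values as deposited, a floor at the median, genes at or above the median only, and leaving out probes near zero on 1 or 2 arrays. A probe counted as near zero where its value was under the 5th percentile of its array while its mean on the other arrays was at or above the median. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.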

Results

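Huh7 is an established human hepatocellular carcinoma cell line. Gene expression was measured on 4 single-colour microarrays of Huh7 cells: 2 arrays of cells carrying a scramble short hairpin RNA (shRNA), the control, and 2 arrays of cells carrying an shRNA against ACOT12. ACOT12 encodes a cytosolic acetyl-CoA thioesterase, an enzyme that splits acetyl-CoA into acetate and coenzyme A. The stated purpose was to find genes downstream of ACOT12 in these cells. The arrays carried 28264 probes, of which 25893 had a gene symbol, giving 19090 genes. The median intensity of the arrays was 377 and 395 for scramble replicates 1 and 2 and 327 and 451 for shACOT12 replicates 1 and 2, and the 75th percentile lay between 2430 and 2657. Nothing in the labels states that the arrays of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. With 2 arrays per group, an exact permutation test could not give a two-sided p below 0.333. The number of arrays therefore limits the precision of every value.

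Across genes, the log2 values of the 2 scramble arrays correlated with a Pearson r of 0.986 and those of the 2 shACOT12 arrays with 0.979, while the 4 pairs of arrays from different groups gave 0.983 to 0.988. Genes are not independent replicates, and these values describe the arrays only. Arrays of the same group were thus no closer to each other than arrays of different groups. Among the brighter genes, the SD of the difference between 2 arrays was 0.508 within scramble and 0.471 within shACOT12, against 0.336, 0.424, 0.462 and 0.530 for the 4 pairs of arrays from different groups, the lowest between the arrays numbered 1 and the highest between shACOT12 replicate 1 and scramble replicate 2.

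ACOT12, the targeted gene, was read by 1 probe (PH_hs_0025727). Its log2 intensity was 7.88 ± 0.57 in scramble and 7.48 ± 0.14 in shACOT12 cells (mean ± SD, n = 2 each). The log2 fold change, shACOT12 minus scramble throughout, was -0.40 (SE 0.35, 95% confidence interval -1.24 to 0.44, limma adjusted p = 1). This difference was smaller than the SD of the scramble replicates, 0.57, and larger than that of the shACOT12 replicates, 0.14. Scramble replicate 1 stood at 8.28, scramble replicate 2 at 7.47, shACOT12 replicate 1 at 7.58 and shACOT12 replicate 2 at 7.37, so the values of the groups overlapped. Without scramble replicate 1 the fold change was 0.0039 and without scramble replicate 2 it was -0.80, both with an adjusted p of 1. The probe was below the median of all arrays, with 35.4% to 46.6% of the probes of an array at or below it, and a reduction of ACOT12 mRNA was not detected.

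In the comparison of shACOT12 with scramble cells, RASD1 fell and was the only one of 19090 genes past the threshold of an adjusted p of 0.05. RASD1 encodes a dexamethasone-inducible Ras-related GTPase. Its deposited intensity was 3122 and 3551 on the scramble arrays and 0 and 12 on the shACOT12 arrays. On the log2 scale it averaged 11.69 ± 0.10 in scramble and 2.03 ± 0.56 in shACOT12 cells (n = 2 each), a log2 fold change of -9.65 (SE 0.35, limma adjusted p = 0.000691). The value rests on 1 probe (PH_hs_0002273), and on the shACOT12 arrays only 0.934% and 0.173% of probes were as low. Normalization gave 2.43 to the 0 on shACOT12 replicate 1, a value shared by all 264 probes set to 1 there. It gave 1.64 to the 12 on shACOT12 replicate 2, which reversed their order, so the SD of 0.56 depends on the floor and the scaling. The size of the change depends on the floor as well: raising values below the 20th percentile of all values to it gave -5.47 (adjusted p = 0.345). The call was also absent with values as deposited, with 75th percentile scaling and with cyclic loess (log2 fold change -9.94 to -9.88), and when any array other than shACOT12 replicate 2 was left out (adjusted p = 0.102 to 1). Near-zero values on exactly 2 arrays against clearly bright values on the others were also read for GABRA2, ANKRD24 and 1 probe without a symbol, each on a pair made of 1 scramble and 1 shACOT12 array.

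At an unadjusted p under 0.05, limma gave 336 genes, 188 higher and 148 lower in shACOT12 cells, where chance alone would give 954. This count was 157 with values as deposited, 180 with 75th percentile scaling and 308 with cyclic loess, and 543, 767, 251 and 751 without scramble replicate 1, shACOT12 replicate 1, scramble replicate 2 and shACOT12 replicate 2. Of the 336, 179 differed at least 2-fold, 98 higher and 81 lower, a count of 228 to 475 without 1 array. The values of the groups did not overlap for 21.5% of genes, against 33.3% by chance. The genes named next were those with the smallest unadjusted p and a difference of at least 2-fold; none passed the adjusted threshold, and their values are given as measured.

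Among the genes with higher values in shACOT12 cells, HDGFL3, a member of the hepatoma-derived growth factor family, averaged 7.37 ± 0.15 in scramble and 11.19 ± 0.47 in shACOT12 cells (n = 2 each), a log2 fold change of 3.81 (SE 0.33, adjusted p = 0.109). Its second probe gave 1.98. HDGFL3 passed the threshold when the prior of the fit followed intensity (adjusted p = 0.00835) and when the dimmest 30% of genes were left out (adjusted p = 0.0206). It also passed with the replicate number as a block and with genes at or above the median only, both described below. HDGFL3 did not pass with values as deposited (adjusted p = 0.99997), cyclic loess (0.152), a robust prior (0.088) or the mean of a gene's probes (0.602). SORL1, a sorting receptor of the LDL receptor family, had a log2 fold change of 1.91 (SE 0.30, adjusted p = 0.887), with 0.67 from its second probe. CT45A2, from a family of cancer/testis antigen genes with near-identical copies that a probe may not tell apart, stood at 2.20 (SE 0.39), and its 3 probes gave 2.20 to 2.50. HSD3B1, a steroid dehydrogenase and isomerase, stood at 1.84 (SE 0.35). DYRK3, a dual-specificity kinase, stood at 1.68 (SE 0.33), but its second probe gave -0.03. DDX60L, a helicase-like gene, stood at 1.49 (SE 0.29), with 1.83 and -0.76 from its other, dimmer probes. The adjusted p was 1 for CT45A2, HSD3B1, DYRK3 and DDX60L.

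Among the genes with lower values, GJA1, which encodes the main gap junction connexin of many cell types, averaged 12.05 ± 0.38 in scramble and 9.25 ± 0.01 in shACOT12 cells (n = 2 each), a log2 fold change of -2.80 (SE 0.31, adjusted p = 0.327). With the prior following intensity its adjusted p was 0.041. GJA1 also passed with the replicate number as a block and with genes at or above the median only, both described below. It did not pass with values as deposited (adjusted p = 0.99997), cyclic loess (0.464), a robust prior (0.281) or the mean of a gene's probes (0.544). NFIB, a transcription factor of the nuclear factor I family, stood at -1.58 (SE 0.30), and its second probe gave -1.50. COL5A3, a chain of type V collagen, stood at -1.30 (SE 0.31) and KRABD1 at -1.19 (SE 0.28). GSTA2 and GSTA1, alpha-class glutathione transferases, stood at -1.18 and -1.14 (SE 0.27 each), with -1.51 from the second probe of GSTA2; the near-identical sequence of these paralogs means that their probes may not tell them apart. The adjusted p was 1 for NFIB, COL5A3, KRABD1, GSTA2 and GSTA1.

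**Figure D1:**
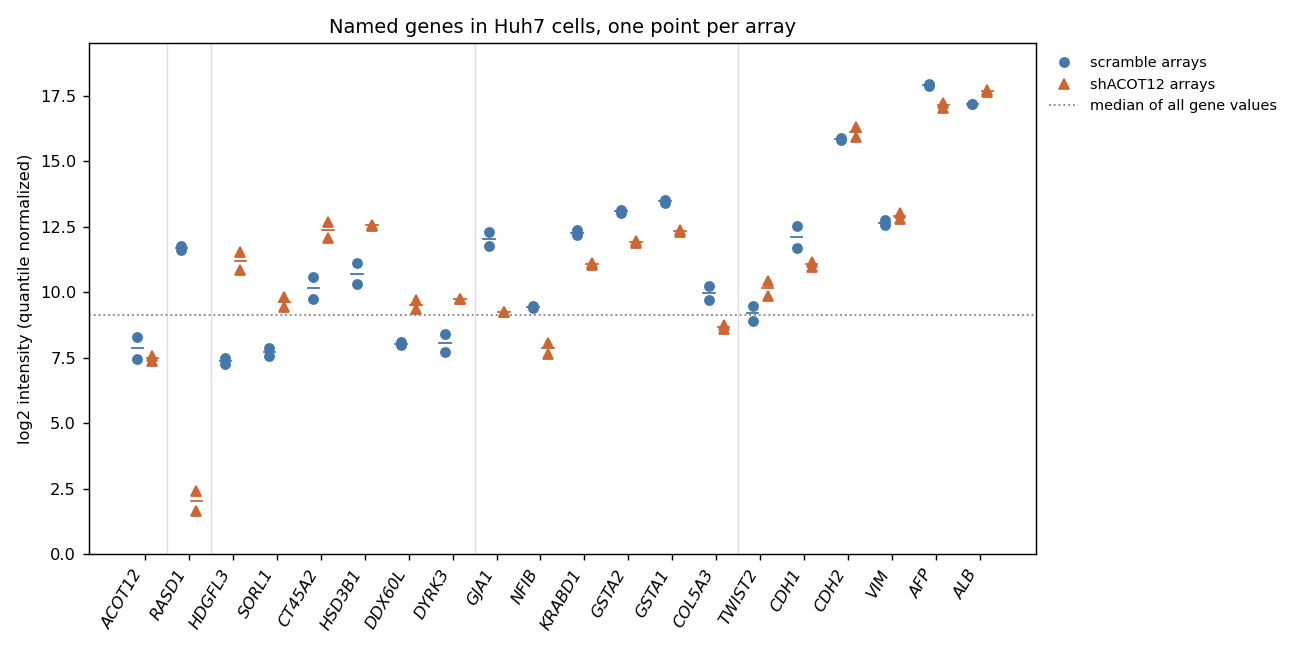
Quantile-normalized log2 intensity (vertical axis) of ACOT12, RASD1, the 12 genes named as not past the threshold and the 6 other genes fixed beforehand, with 1 point per array (circles scramble, triangles shACOT12), short lines for the means of 2 arrays and a dotted line at the median of all gene values, 9.14. RASD1 is the gene whose shACOT12 values, 2.43 and 1.64, lie near the bottom of the scale.

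Genes of epithelial and mesenchymal state and of liver identity that had been fixed beforehand did not pass the threshold over all genes (adjusted p = 1 for each). TWIST2, a basic helix-loop-helix transcription factor, averaged 9.19 ± 0.40 in scramble and 10.15 ± 0.40 in shACOT12 cells (n = 2 each), a log2 fold change of 0.96 (SE 0.35). CDH1, which encodes E-cadherin, averaged 12.10 ± 0.61 and 11.07 ± 0.12, a log2 fold change of -1.04 (SE 0.36). AFP, which encodes alpha-fetoprotein, stood at 17.91 ± 0.03 and 17.13 ± 0.15, a log2 fold change of -0.78 (SE 0.28). Adjusted over the list alone, that is over these 6 genes and ACOT12, limma gave 0 genes past the threshold, and the adjusted p was 0.0679 for each of TWIST2, CDH1 and AFP. The mesenchymal genes CDH2 (N-cadherin) and VIM (vimentin) stood at 0.29 (SE 0.29) and 0.25 (SE 0.28), both with an adjusted p of 0.401 over the list alone, and ALB (albumin) at 0.49 (SE 0.27), with 0.197. The values of the groups did not overlap for any of these 6 genes, as for 21.5% of all genes and for 33.3% by chance. For VIM the nearest values were 12.76 on scramble replicate 1 and 12.79 on shACOT12 replicate 1. Without 1 array CDH1 ranged from -1.47 to -0.61, TWIST2 from 0.68 to 1.24, CDH2 from 0.09 to 0.48 and VIM from 0.13 to 0.38.

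Of the 34 gene lists fixed beforehand, limma's camera with a preset inter-gene correlation called 1, the replication-dependent histone genes, which rose as a group. None of its 18 measured members passed the threshold by itself, over all genes or adjusted over the list alone, but 16 of the 18 were higher in shACOT12 cells, with a median log2 fold change of 0.39 and a mean shift over all genes of 0.40 (camera adjusted p = 3.7e-05). The call was lost with an estimated inter-gene correlation (adjusted p = 0.738), a test that raised p also for lists with an estimated correlation below 0. Fry, which tests whether the members move on balance one way and not against other genes, gave an adjusted p of 0.771. H2AC6 averaged 9.46 ± 0.72 in scramble and 10.26 ± 0.52 in shACOT12 cells, a log2 fold change of 0.80, and H2BC12 averaged 14.55 ± 0.31 and 15.18 ± 0.03, a log2 fold change of 0.62 (n = 2 each, adjusted p = 1 for both). The values of the groups overlapped for H2AC6, and without 1 array H2AC6 ranged from 0.29 to 1.31 and H2BC12 from 0.40 to 0.84. The mean log2 value of the list was 10.02 and 9.58 on scramble replicates 1 and 2 and 10.33 and 10.07 on shACOT12 replicates 1 and 2. Without scramble replicate 2 the shift was 0.18 (adjusted p = 0.253) and without shACOT12 replicate 1 it was 0.26 (adjusted p = 0.241), while without scramble replicate 1 it was 0.63. The median ranged from 0.14 to 0.61 without 1 array, with 12 of 18 members higher without scramble replicate 2.

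None of the other 33 lists passed the threshold, no list passed it with an estimated correlation or with fry, and in all 34 lists 0 members passed by themselves, over all genes or adjusted over the list alone. Before adjustment, limma's camera put 8 lists under a p of 0.05. The acyl-CoA thioesterase family, to which ACOT12 belongs, had 6 of 11 members higher (camera adjusted p = 0.107), among them ACOT4, a peroxisomal acyl-CoA thioesterase, at 1.02 (SE 0.28) and THEM4 at 0.46 (SE 0.29). Its mean of 0.23 lay above its median of 0.03, with ACOT6 at 0.97 and THEM5 at 0.80, both dim. Without 1 array the mean shift of this family ranged from 0.14 to 0.33, its median from 0.0039 to 0.23, ACOT6 from 0.65 to 1.30 and THEM5 from 0.40 to 1.19. Acetyl-CoA and acetate metabolism had 14 of 24 members higher (adjusted p = 0.992), with DLAT, a subunit of pyruvate dehydrogenase, at 0.35 (SE 0.30; second probe -0.0095) and ACSS2, the cytosolic acetyl-CoA synthetase, at -0.28 (SE 0.40); its mean and median were above 0 while camera's direction was down. Fatty acid and triglyceride synthesis had 12 of 24 higher (adjusted p = 0.431), with a median above 0 and a mean below 0. Its ACACB, an acetyl-CoA carboxylase, stood at -0.63 (SE 0.37; second, dimmer probe 0.10) and MLXIPL, a carbohydrate-responsive transcription factor, at -0.57 (SE 0.38). Cholesterol synthesis had 11 of 20 members lower (adjusted p = 0.612), with EBP at -0.43 and SC5D at -0.32 (SE 0.29 and 0.28), both enzymes of the late pathway. Leaving out 1 array moved several of these values, with ranges of 0.28 to 0.64 for THEM4, 0.12 to 0.57 for DLAT, -0.76 to 0.20 for ACSS2, -0.97 to -0.29 for ACACB, -0.97 to -0.18 for MLXIPL, -0.62 to -0.25 for EBP and -0.44 to -0.20 for SC5D.

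Fatty acid oxidation genes were lower for 20 of 27 members, with a mean shift of -0.14 that did not pass (adjusted p = 0.0742). CPT1A, which carries out the entry step of long-chain fatty acids into mitochondria, stood at -0.62 (SE 0.31) and ACADS at -0.50 (SE 0.30). Hepatocyte metabolic and detoxification enzymes, with GSTA2 and GSTA1 as the leading members, were lower for 28 of 41 (shift -0.18, adjusted p = 0.0612). Hepatocyte secreted proteins were lower for 22 of 34 (shift -0.13, adjusted p = 0.0768), with SERPINC1 (antithrombin) at -0.99 (SE 0.30), whose second probe gave -0.05, and F2 (prothrombin) at -0.50 (SE 0.33). Liver transcription factors and nuclear receptors were lower for 11 of 17 (shift -0.17, adjusted p = 0.0858), with PPARG at -0.59 (SE 0.37) and CEBPB at -0.58 (SE 0.42). NRF2 antioxidant targets were lower for 16 of 25 (shift -0.10, adjusted p = 0.0768), with AKR1C1 at -0.80 (SE 0.37) and TXNRD1 at -0.59 (SE 0.28). With an estimated correlation the adjusted p was 0.738 for each of these 5 lists and for the epithelial list, but under other settings chosen before the data were examined, with the preset correlation, each of the 5 passed in some. Fatty acid oxidation and hepatocyte enzymes passed with the dimmest 30% of genes left out (adjusted p = 0.0387 and 0.0177), with the mean of a gene's probes (0.038 and 0.0449), with 1 row per probe (0.0114 and 0.00799) and without scramble replicate 1 (0.00925 and 0.0202), and the hepatocyte enzymes also with 75th percentile scaling (0.0382). Hepatocyte secreted proteins passed with the mean of probes (0.0449), by probe (0.0246) and without scramble replicate 2 (0.00932), liver transcription factors with the dimmest 30% left out (0.0387) and without scramble replicate 1 (0.0269), and NRF2 targets with a floor at the 20th percentile (0.0336). By probe, several probes of the same gene counted as separate members, which can make camera's p too small. Single arrays moved the shifts of these lists: leaving out each array in turn gave -0.27 to -0.016 for fatty acid oxidation, -0.26 to -0.11 for hepatocyte enzymes, -0.25 to -0.014 for secreted proteins, -0.29 to -0.054 for liver transcription factors and -0.23 to 0.018 for NRF2 targets. The number of lower members ranged from 20 to 27 for hepatocyte enzymes and from 14 to 27 for secreted proteins. Among their genes, CEBPB ranged from -1.12 to -0.033, PPARG from -1.04 to -0.14, F2 from -0.83 to -0.16, CPT1A from -0.89 to -0.35, ACADS from -0.71 to -0.29 and AKR1C1 from -1.22 to -0.37.

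Epithelial junction and keratin genes were lower for 21 of 29 members (median -0.10, adjusted p = 0.0612), with CDH1 at -1.04 and TJP1, a tight junction scaffold, at -0.45 (SE 0.28). The shift of this list depended on DSP, a desmosomal plaque gene that was near zero on scramble replicate 1 alone and had a log2 fold change of 4.88 (SE 2.93; -0.45 without scramble replicate 1 and 10.21 without scramble replicate 2): the shift was -0.039 with DSP and -0.22 without the probes that were near zero on 1 or 2 arrays (adjusted p = 0.021, an alternative chosen after the data were seen). The epithelial list also passed with the preset correlation in settings chosen beforehand. These were 75th percentile scaling (adjusted p = 0.0382), the dimmest 30% of genes left out (0.0147), a floor at the 20th percentile (0.0213), the mean of probes (0.0254) and 1 row per probe (0.00799). In the last of these, several probes of the same gene counted as separate members. With an estimated correlation camera's adjusted p for this list was 0.738. Its shift ranged from -0.19 to 0.11 without 1 array. Mesenchymal and EMT transcription factor genes had 16 of 29 members lower (adjusted p = 0.643), 9 to 17 lower without 1 array, with S100A4 at -1.07 (SE 0.48, -1.72 to -0.43 without 1 array) beside TWIST2 at 0.96. The oncofetal and liver progenitor genes had 13 of 23 higher (adjusted p = 0.821), with SPINK1, a secreted trypsin inhibitor, at 1.04 (SE 0.27) beside AFP at -0.78. Histone acetyltransferases were lower for 7 of 14 (adjusted p = 0.615), with KAT7 at -0.38 (SE 0.27) and KAT2A at 0.34 (SE 0.30), and histone deacetylases for 12 of 18 (adjusted p = 0.268), with HDAC8 at -0.60 (SE 0.29) and HDAC11 at -0.57 (SE 0.43), whose second probe gave 0.07. Mitotic and DNA replication genes were lower for 23 of 41 (adjusted p = 0.311), with KIF20A at -0.45 (SE 0.32) and BIRC5 at -0.40 (SE 0.27), whose other probes gave -0.08 and 0.28. Without 1 array KAT2A ranged from 0.15 to 0.53, HDAC8 from -0.82 to -0.39, HDAC11 from -1.19 to 0.045 and KIF20A from -0.73 to -0.17.

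The remaining lists had camera adjusted p-values of 0.268 or more. Hypoxia and glycolysis genes had 18 of 30 members lower (adjusted p = 0.268), OXPHOS genes 21 of 32 (0.346), interferon-stimulated genes 20 of 35 (0.346), p53 targets 14 of 22 (0.346), immediate early and MAPK feedback genes 18 of 26 (0.346), acute phase proteins 12 of 18 (0.367), TGF-beta targets 13 of 23 (0.564), ribosomal proteins 24 of 39 (0.657), unfolded protein response genes 15 of 28 (0.671) and WNT targets 10 of 19 (0.68). Collagens, laminins and integrins had 18 of 30 higher (0.346), cytosolic heat shock genes 11 of 17 (0.657) and NF-kB and inflammatory cytokine genes 11 of 27, with a median below 0 but a mean above it (0.612). Without 1 array the number of higher members ranged from 5 to 14 for the heat shock genes and from 13 to 18 for the NF-kB genes, and that of lower members from 12 to 22 for the hypoxia genes. No list of markers of cell types other than hepatocytes passed: the adjusted p was 0.469 for stellate cell and fibroblast markers, 0.469 for leukocyte markers, 0.751 for bile duct cell markers, 0.768 for endothelial markers, whose median and mean also differed in sign, and 0.917 for red cell lineage markers.

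**Figure D2:**
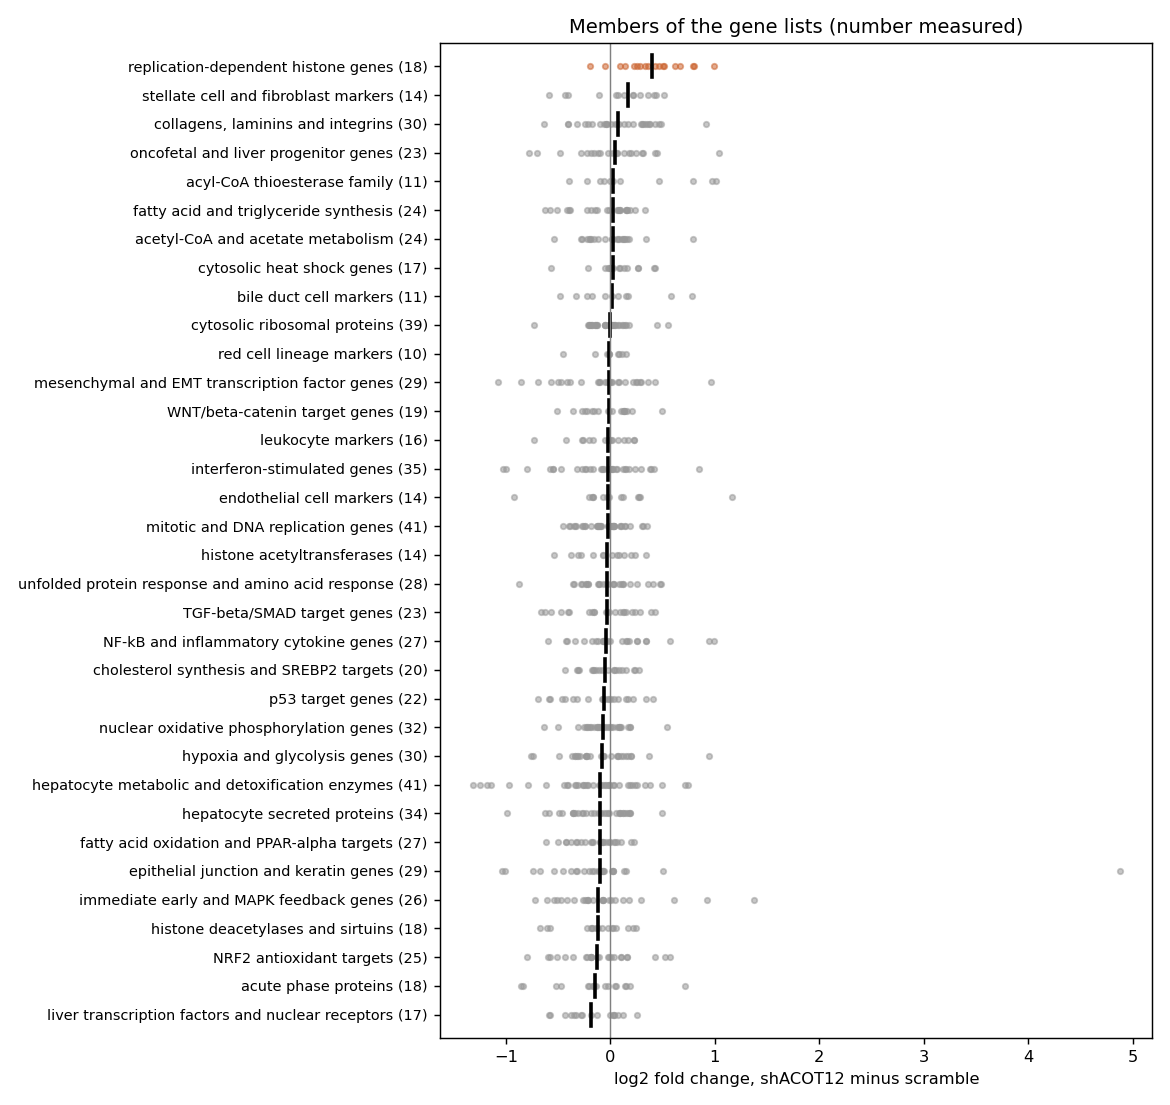
Log2 fold change, shACOT12 minus scramble (horizontal axis), of each measured member (points) of the 34 gene lists (vertical axis, number of measured members in brackets), with black bars at the medians and the list called by camera with its preset correlation in colour. The replication-dependent histone genes have the highest median, 0.39, and the point at 4.88 among the epithelial genes is DSP.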

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

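The alternatives with values as deposited, with a floor at the median, with genes at or above the median only and without near-zero probes were chosen after the data were seen. The quantile alternative was the setting used and has no value of its own. The count of 1 gene past the adjusted threshold, RASD1, was also 1 with a robust prior, with the mean of a gene's probes, with 1 row per probe and with the dimmest 30% of genes left out, where the gene was HDGFL3, since RASD1 was itself left out. It was 3 with an intensity trend (RASD1, HDGFL3 and GJA1), 2 with genes at or above the median only (HDGFL3 and GJA1) and 0 with values as deposited, 75th percentile scaling, cyclic loess, a floor at the 20th percentile, a floor at the median, without near-zero probes (RASD1 being one of these) and with a plain t-test without moderation. With the 2-fold limit the counts were the same, with 1 by treat and 179 at an unadjusted p. Leaving out each array in turn gave 0 to 4 genes; the 4, without shACOT12 replicate 2, were RASD1, LARP4B, TMEM213 and GRB10, of which the last 3 were near zero on shACOT12 replicate 1 alone. These fits assume that the lone array varies like the other group. The RASD1 log2 fold change ranged from -10.05 to -9.26 without 1 array and was -5.47 and -3.10 with the floors at the 20th percentile and the median. The causes of the lost calls were not tested beyond this.

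Arrays with the same replicate number share only that number here, with 2 pairs and no statement of a shared culture or batch. Their deviations from the group means correlated at 0.18 after quantile normalization and at -0.044 as deposited. With the replicate number as a block, 25 genes passed the threshold, 13 higher and 12 lower, among them RASD1, HDGFL3 (adjusted p = 1.7e-05), GJA1 (0.000789) and CT45A2, and all 25 differed at least 2-fold. In this fit 704 genes had an unadjusted p under 0.05, below the 954 that chance alone would give. The block leaves fewer residual degrees of freedom than the 2 of the main fit, so these p-values lean more on the prior. The histone list stayed called.

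ACOT12 ranged from -0.80 to 0.0039 without 1 array and was 0 with the floor at the median, where all its values lie at the floor. Among 791 values of named genes under the alternatives, 3 had the opposite sign and 1 was 0: these values of ACOT12, and ACSS2 (range -0.76 to 0.20) and HDAC11 (range -1.19 to 0.045), both without scramble replicate 2.

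The count of 1 list called by camera was 3 with 75th percentile scaling, the floor at the 20th percentile and genes at or above the median only, 5 with the dimmest 30% left out, the mean of probes, 1 row per probe and the floor at the median, 2 without near-zero probes, 0 with an estimated correlation or fry, and 0 to 7 without 1 array. The histone list was among the lists called except with an estimated correlation (shift 0.40, adjusted p = 0.738), with fry (adjusted p = 0.771 for its members moving on balance one way, a test that does not compare them with other genes) and without shACOT12 replicate 1 or scramble replicate 2; its shift without 1 array ranged from 0.18 to 0.63. The further lists called were the epithelial, hepatocyte, fatty acid oxidation and NRF2 lists in the settings given with them, the epithelial and hepatocyte enzyme lists also with genes at or above the median only, the epithelial, liver transcription factor, NRF2 and OXPHOS lists also with the floor at the median, and the heat shock, hypoxia and MAPK lists without scramble replicate 1.

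Of 637 list shifts under the alternatives, 41 had the opposite sign, none of them of the histone list; the cause was not tested. The ribosomal list was at 0.043 with values as deposited and with 75th percentile scaling and 0.0031 with genes at or above the median only. The acetyl-CoA list was at -0.00098 without the dimmest 30%, -0.00095 with the 20th percentile floor, -0.034 with the mean of probes, -0.020 by probe and -0.0099 with genes at or above the median. The endothelial list was at -0.046 and -0.029 with the lower and higher floor, the bile duct list at -0.019 and -0.0022, and the red cell list at 0.010 and 0.032, with 0.045 for the mean of probes and 0.093 by probe. The oncofetal list was at -0.0053 for the mean of probes and -0.00071 by probe, and the unfolded protein response list at 0.024 by probe. Without 1 array the shifts ranged from -0.082 to 0.087 (acetyl-CoA), -0.19 to 0.11 (epithelial), -0.017 to 0.058 (oncofetal), -0.14 to 0.016 (mitotic), -0.20 to 0.0047 (interferon), -0.013 to 0.12 (NF-kB), -0.076 to 0.020 (unfolded protein response), -0.23 to 0.36 (heat shock), -0.23 to 0.018 (NRF2), -0.28 to 0.085 (hypoxia), -0.057 to 0.0098 (ribosomal), -0.077 to 0.018 (WNT), -0.19 to 0.067 (MAPK), -0.088 to 0.16 (endothelial), -0.17 to 0.015 (leukocyte), -0.056 to 0.15 (bile duct) and -0.15 to 0.10 (red cell).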

Other observations

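The tests on scramble replicate 2 alone, on replicate numbers and on splits under other scalings, and the families described next, were chosen after the results had been seen. Among the alpha-class glutathione transferases, which conjugate glutathione to hydrophobic compounds, GSTA3 stood at a log2 fold change of -1.26 (SE 0.33), close to GSTA2 at -1.18 and GSTA1 at -1.14, while GSTA5 stood at -0.26 and GSTA4 at 0.22 (adjusted p = 1 for each). The median over these 5 genes was -1.14 after quantile normalization, -1.15 with values as deposited, -1.12 with 75th percentile scaling and -1.15 with cyclic loess. GSTA4 and GSTA5 changed sign when 1 array was left out: GSTA4 was at -0.032 without scramble replicate 1 and 0.47 without scramble replicate 2, and GSTA5 at -0.63 and 0.11. GSTA1, GSTA2 and GSTA3 are close in sequence, and their probes were not shown to be independent. In the CT45A family, CT45A2 stood at 2.20 and CT45A5 at 0.07, with values of -0.25 to 0.39 for CT45A5 without 1 array.

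Of 42 measured histone genes outside the list fixed beforehand, not tested as a group, 31 were higher and 11 lower in shACOT12 cells, with a median log2 fold change of 0.29, and 35 to 37 were higher under the other scalings. Most of them were dim, with means below the median of all gene values, 9.14, among them H2AC13 (7.85 in scramble and 8.99 in shACOT12 cells). H2AC13 stood at 1.14 (SE 0.42) and H2AC14 at 0.90 (SE 0.44), while H2BC17 stood at -0.51 (SE 0.43), all with an adjusted p of 1; without 1 array H2AC13 ranged from 0.71 to 1.57, H2AC14 from 0.32 to 1.48 and H2BC17 from -1.12 to 0.096. The median was 0.12 without scramble replicate 2, with 27 of 42 higher, 0.24 without shACOT12 replicate 1 (29 higher), 0.42 without scramble replicate 1 (37 higher) and 0.54 without shACOT12 replicate 2 (35 higher). Many of these genes share sequence with members of the list and are not independent of it.

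The first pattern is RASD1 near zero on both shACOT12 arrays. Losses of single spots that are independent between arrays predict 0.000639 probes lost on both shACOT12 arrays (a count of 0 on an array was raised to a floor of 3, a choice made after the counts were seen), which argues against that explanation. Outside this pair, 4 probes were near zero on exactly 2 arrays, those of GABRA2, ANKRD24, DEF8 and 1 unnamed probe, although DEF8 was separated by only 0.85 on the log2 scale from the nearest brighter array. These 4 probes were spread over different pairs, and RASD1 was the only probe near zero on exactly the 2 shACOT12 arrays. They therefore do not show a print shared by those 2 arrays, nor exclude it. Spots missing on a pair of arrays could still account for RASD1, and a lower RASD1 level in shACOT12 cells stays open as well. A second probe, which these arrays do not give, would bear on this.

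The second pattern is the shift of the replication-dependent histone genes. Members that move together between arrays could account for its small camera p: the estimated correlation between members was 0.206 and camera's p with it was 0.131. That estimate lay above the preset of 0.01, and if it holds, the p at the preset is too small. How much of the rise in p comes from it is not shown. Camera with an estimated correlation rests on 2 residual degrees of freedom and raised p for other lists too. For the acyl-CoA thioesterase family, with an estimated correlation of -0.081, camera's p went from 0.0253 to 0.144. A low value on scramble replicate 2 alone stays open. Without that array the shift was 0.180 against 0.40 on all arrays, but leaving out the lower control must reduce it. Leaving out shACOT12 replicate 1, the higher shACOT12 array for this list, must reduce it too (0.26). Neither value therefore decides this. Histone genes are transcribed mainly in S phase and most of their mRNAs lack a poly(A) tail, so a difference in cell cycle or in the priming of the amplification could move them together; neither was tested here, beyond the mitotic and DNA replication list, which was lower for 23 of 41 members and did not pass. An effect of the ACOT12 shRNA stays open.

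The third pattern is the low number of genes past the threshold: the labelled split of the 4 arrays gave 336 genes with an unadjusted p under 0.05 (1 past the adjusted threshold), the split by replicate number 2072 (2 adjusted) and the other split 533 (0 adjusted), and 3 splits are too few for a share under 0.05. Under the other scalings the labelled split again gave the fewest at an unadjusted p (157 to 308), but the split by number gave 1381 against 1140 for the other split with values as deposited, 1184 against 1325 with 75th percentile scaling and 1979 against 555 with cyclic loess, genes past the adjusted threshold were found only in the other split as deposited (14) and with 75th percentile scaling (17) and in no split with cyclic loess, and the deviations of same-numbered arrays correlated at 0.18 after quantile normalization and -0.044 as deposited, so the samples have a structure that the labels do not follow, and whether it follows the replicate number depends on the scaling. A technical difference shared by arrays of 1 number, which the 2072 genes alone would favour, and an exchange of the labels of scramble replicate 2 and shACOT12 replicate 1, for which they would have counted by the test set beforehand, predict the same split, while an exchange of the 2 labels of 1 number predicts the other split; the values do not tell these apart, a reading made after the counts were seen. After quantile normalization ACOT12 stood at 8.28 and 7.58 on the arrays numbered 1 and at 7.47 and 7.37 on those numbered 2. These values did not overlap and lay in the direction an exchange would give. Chance alone gives no overlap for 33.3% of genes, and a replicate effect could give it too. In the other split the normalized values overlapped. As deposited, ACOT12 was 302 and 156 on the arrays numbered 1 and 178 and 207 on those numbered 2. These deposited values overlapped by number and not in the other split, so ACOT12 does not tell the splits apart either. The size of the experiment is a further candidate explanation: in simulated data with this spread 0.470% of genes changed 2-fold were called, and a small effect of the shRNA stays open, untested.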
